A study of Homo sapiens with 2 samples.

How the data were processed

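The series held 2 single-colour arrays, 1 of MCF-7 cells with shGATA3 and 1 with shSCR, and the groups were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and a miRNA isolation kit, and 0.2 µg was labelled with Cy3. Per the file headers, the arrays were of Agilent design 046064, annotated on hg19, and were scanned at 20 bits and read with Agilent Feature Extraction 11.5.1.1. The deposited scanner files gave the intensity of each spot after the software had subtracted the background and a spatial trend, with no normalization between arrays, per the file headers and the values. Both arrays were on the same slide at neighbouring positions, so slide and scan did not differ between the groups, while array position and group could not be told apart. The number of arrays limits the precision.

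The authors' deposited value table was on a log2 scale. Set against the scanner files, each of its columns equalled log2 of the software's total signal per miRNA minus 1 constant per array, 3.78 for shGATA3 and 3.34 for shSCR, with a largest deviation of 1.0e-05 over 2027 rows. The rule behind the constants is not given in the sources used here, although 90.0% of rows lay below the constant on each array. Column medians were -7.10 and -6.66, which reflect miRNAs at the floor. The direction of the table was settled by this match and its centring was not.

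Here, control spots and spots with outlier flags (3134 in shGATA3, 1994 in shSCR) were left out, and no spot was saturated. Processed signals were taken to log2 and averaged over the spots of a probe. A probe was detected on an array when at least 50% of its kept spots were well above background. Each array's values were taken relative to its 75th percentile over the 402 probes detected on both arrays, which removed an offset of 0.28 on the log2 scale (1.21-fold). The difference of a miRNA was the mean over its probes detected on both arrays. Names are those of the array design, without the species prefix. No spot of a detected probe was at or below 0. The negative-control spots had median intensities of 2.30 in shGATA3 and 5.15 in shSCR, and the dimmest detected probes 24.0 and 17.1.

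A miRNA was counted at a difference of at least 1 in either direction (2-fold). Named miRNAs were, by a rule set before the data were examined, up to 12 per direction with the highest and lowest differences among those past 2-fold whose shared probes all went the same way and whose brighter level was at least 4 times the lowest detected one. The rule also took the 5 miRNAs with the largest bound in each direction among those detected on 1 array, and members of 22 fixed lists. The rule was met by 15 higher and 5 lower miRNAs. miR-106a-5p and miR-519a-3p were not on the array under those names. A list's median difference was set among 10000 random lists of the same size, drawn within 5 bins of mean level. A percentile describes these 2 arrays and is no test. Members of a family or cluster can share a neighbourhood or a sequence, which the random lists do not copy.

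The alternatives were 11 settings planned beforehand (other scalings, normexp correction, the total signal per miRNA, the deposited table, the brightest probe, stricter and looser detection and brightness filters), other thresholds and detection rules, and 3 scalings added after the data were seen. Normexp with an offset of 50 was run in limma 3.58.1 on median spot and background intensities, because mean spot intensities were not among the columns used. In the setting without a filter on dim probes, every value under the lowest detected one was set to that value. The steps were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3. They were tested on simulated data for this comparison with 243 miRNAs. All 15 miRNAs changed by 1.5 and all 15 changed by -1.5 on the log2 scale were counted, and none of those changed by 0.75, -0.75 or 0. Both simulated arrays were drawn from the shSCR array with its spot noise, and variation between arrays, labellings or cultures was not simulated. The simulation therefore checks the calculation and gives no rate of false calls for 1 array per group. RefSeq gene names of assembly GRCh38.p14 were used only to find neighbouring miRNA genes, and 220 of 229 miRNAs matched a gene. No probe sequences or genome were used, so base composition was not tested.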

Results

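MicroRNAs were profiled in MCF-7 cells, an established human breast cancer line of luminal, oestrogen-receptor-positive origin. The cells stably carried either a short hairpin against GATA3 (shGATA3) or a control hairpin (shSCR). GATA3 encodes a zinc-finger transcription factor of the luminal mammary lineage. Total RNA of each was labelled with Cy3 and hybridised to 1 single-colour miRNA array, so there were 2 arrays and n = 1 per group. The comparison therefore has no replicate check, no test and no p-value, and every difference below compares these 2 arrays, not the conditions at large. The error given as ± is the SD among replicate spots of a probe, combined over both arrays, and covers technical error within an array only. GATA3 mRNA was not measured by these arrays, so the extent of the knockdown is not checked here.

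Each array carried 62344 spots, of which 60180 were for 2006 human miRNAs and 2164 were controls. Of the miRNA spots, 11.3% were well above background in shGATA3 and 10.5% in shSCR. In shGATA3, 248 miRNAs were detected, against 243 in shSCR. Of these, 229 were detected on both arrays, 19 in shGATA3 only and 14 in shSCR only, and 1744 were not well above background on either. The levels of the 229 shared miRNAs correlated with a Pearson r of 0.96 across miRNAs, which are not independent replicates. Of 15 miRNAs taken as typical of stroma, blood, liver, muscle or brain, 14 were not well above background on either array. The blood-cell miRNA miR-486-5p was detected in shGATA3 only. Outside these 15, miR-219-5p of the fixed list for liver, muscle, heart or brain was detected on both arrays. The epithelial miRNAs miR-200c-3p, miR-141-3p, miR-203a and miR-205-5p were detected on both arrays.

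The first question was which miRNAs differed between cells with the GATA3 hairpin and control cells. In shGATA3, 17 of the 229 shared miRNAs were at least 2-fold higher and 5 were at least 2-fold lower, and the other 207 lay within 2-fold. The lower miRNAs included miR-342-3p, a miRNA of oestrogen-receptor-positive breast tumours, which was 2.93-fold lower (log2 difference -1.55 ± 0.12). miR-205-5p, an epithelial miRNA of basal mammary cells, was 2.90-fold lower (-1.54 ± 0.28). miR-210, which is induced by hypoxia, was 2.36-fold lower (-1.24 ± 0.15). miR-1275 was 2.24-fold lower (-1.16 ± 0.17) and miR-652-3p was 2.17-fold lower (-1.12 ± 0.22). Without scaling, miR-210 (-0.96), miR-1275 (-0.88) and miR-652-3p (-0.84) lay within 2-fold, as they did with hybridisation spike-ins (-0.92, -0.85 and -0.80). With normexp, miR-205-5p (-0.70), miR-210 (-0.83), miR-1275 (-0.60) and miR-652-3p (-0.55) lay within it. miR-1275 was at -0.95 by its brightest probe, and miR-652-3p at -0.56 without a dim filter.

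**Figure D1:**
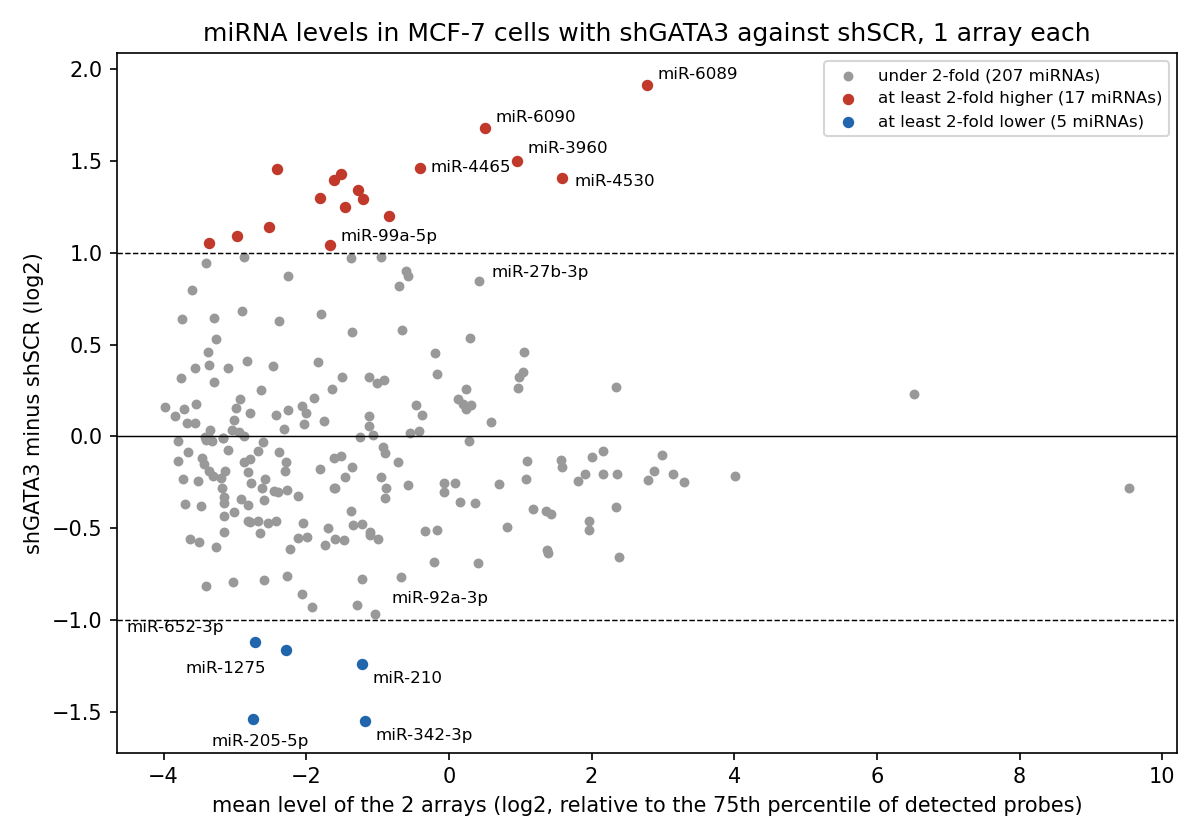
Difference between shGATA3 and shSCR (log2, vertical axis) against the mean level of the 2 arrays (log2, relative to the 75th percentile of detected probes, horizontal axis) for 229 miRNAs, 1 point each, with dashed lines at 2-fold. The 17 miRNAs at least 2-fold higher reach 1.92 for miR-6089, and the 5 lower ones reach -1.55 for miR-342-3p.

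The higher miRNAs were mostly ones named late in the numbering of human miRNAs. miR-6089 had the highest difference, with a level 3.77-fold higher in shGATA3 (1.92 ± 0.065). It was followed by miR-6090 at 3.20-fold (1.68 ± 0.065) and miR-3960 at 2.82-fold, with a spot SD of 0.074 on the log2 scale. miR-4465, miR-6126, miR-4687-3p, miR-4530 and miR-6088 were between 2.63-fold and 2.75-fold higher. miR-1207-5p was 2.54-fold higher, miR-762 2.46-fold, miR-3665 2.45-fold and miR-1915-3p 2.38-fold. With normexp, 7 of these 12 lay within 2-fold (miR-6126, miR-4687-3p, miR-6088, miR-1207-5p, miR-762, miR-3665 and miR-1915-3p), and so did miR-6126 (0.73) and miR-762 (0.97) without a dim filter. Of the 17, 14 had numbers of 1000 or more, as did 90 of the 229 shared miRNAs. Those 90 were not higher as a group: their median difference was -0.15, against -0.11 for the 139 numbered under 1000. Their differences were more widely spread (SD 0.71 against 0.47). The other 3 of the 17 were miR-762, miR-572 and miR-99a-5p, of which miR-572 was outside the naming rule and is given after its value was seen (1.05 ± 0.30). miR-99a-5p, a member of the miR-99 family, was 2.06-fold higher (1.04 ± 0.20). Both miR-99a-5p and miR-572 lay within 2-fold with normexp (0.52 and 0.17), the total signal (0.88 and 0.89) and the deposited table (0.87 and 0.88), as did miR-99a-5p with all spots above background (0.87) and miR-572 without a dim filter (0.53).

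These differences exceeded the spread between spots. When the spots of each shared probe on a single array were split at random into 2 sets, no miRNA reached 2-fold in any of 100 draws, and the highest difference was 0.45. Different probes of a miRNA differed by a median gap of 0.057 on the log2 scale over the 164 miRNAs with several shared probes, and probes of 11 miRNAs had opposite signs. The gap was highest, at 0.62, for miR-4687-3p (probes at 1.12 and 1.74), and the probes of miR-6088 were at 1.14 and 1.65, of miR-4466 at 0.96 and 1.33 and of miR-6089 at 1.76 and 2.07. The balance of higher and lower miRNAs differed between processing settings, some of which changed the summary or the miRNAs tested as well as the scaling. It was 17 against 5 in the main setting, 27 against 2 without scaling or with scaling on the hybridisation spike-ins, 18 against 20 in the authors' deposited table and 18 against 18 with the scanner software's sum per miRNA. With probes detected only where all spots were well above background it was 13 against 9, and with normexp background correction only 5 and 1 remained past 2-fold.

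**Figure D2:**
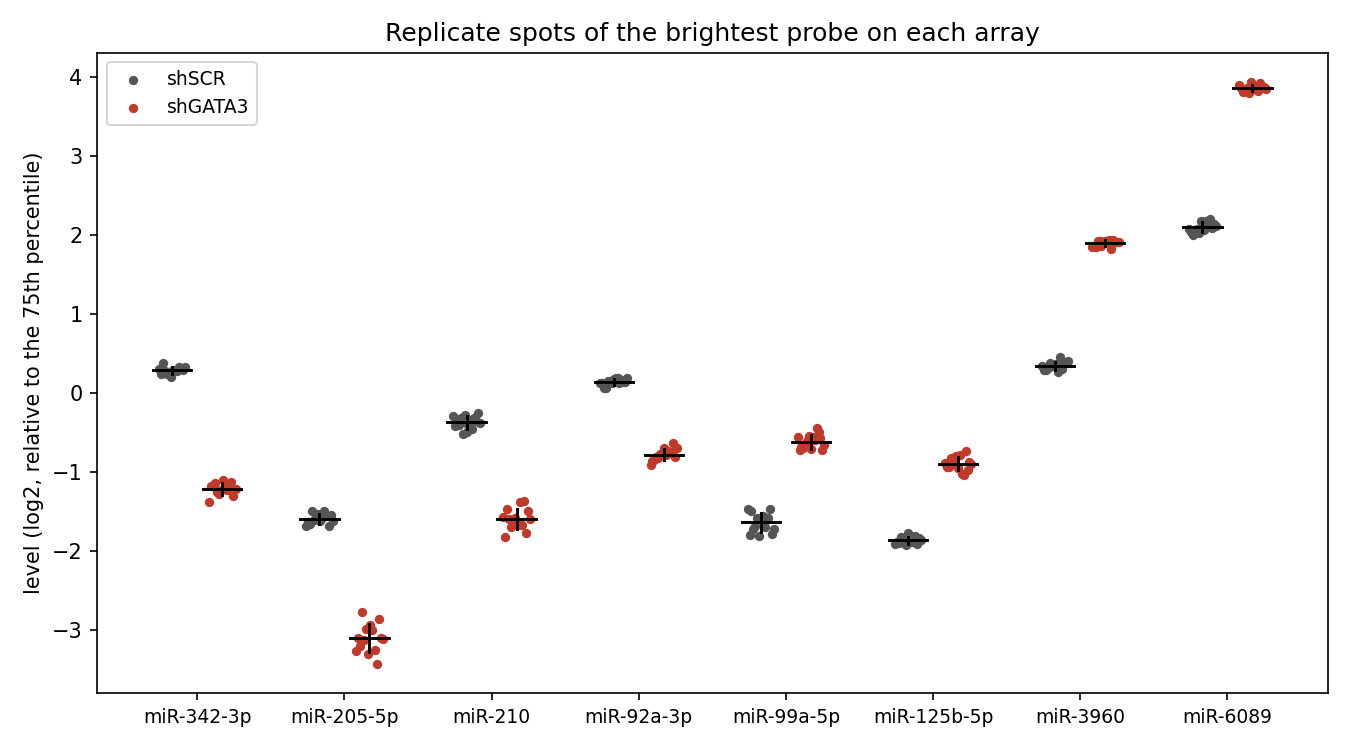
Levels of the replicate spots (points) of the brightest probe of 8 miRNAs in shSCR (grey) and shGATA3 (red), on a log2 axis relative to the 75th percentile of detected probes, with the mean and SD over spots as black lines. The spots of the 2 arrays do not overlap for any of the 8 miRNAs, of which miR-342-3p, miR-205-5p, miR-210 and miR-92a-3p were lower in shGATA3.

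The next comparison was by miRNA families and lists fixed before the data were examined. Over all 229 shared miRNAs, 136 were lower and 93 higher in shGATA3, with a median difference of -0.12, against which the lists are to be read. All 11 detected members of the miR-17-92 cluster and its paralogs, a growth-promoting group of miRNAs often amplified in tumours, were lower in shGATA3, as were 10 of 11 without scaling or with scaling on the hybridisation spike-ins. Their median difference was -0.49, at percentile 0.12 of random lists of the same size and level. Many of the 11 share a gene neighbourhood or a similar sequence, so they are not independent values. The random lists do not copy this, and the percentile may look more extreme than it is. Signal shared between probes of similar miRNAs was not tested. Within this group, miR-92a-3p was 1.95-fold lower (-0.97 ± 0.11) and miR-17-5p 1.61-fold lower (-0.69 ± 0.10). The smallest difference of the group was that of miR-106b-5p (-0.10 ± 0.086). In the main setting no member reached 2-fold, whereas miR-92a-3p was past it with quantile normalization (-1.03), the total signal (-1.09), the deposited table (-1.10) and all spots above background (-1.13). The median stayed below 0 in all 14 alternative settings, between -0.66 and -0.18.

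Members of the miR-23/27/24 clusters were higher in 4 of 5 cases, with a median of 0.32 at percentile 95.71. miR-27b-3p was 1.80-fold higher (0.84 ± 0.093) and miR-23b-3p 1.45-fold higher (0.54 ± 0.082), whereas miR-23a-3p had a difference of -0.13 ± 0.053. The median of the clusters stayed above 0 in all 14 alternatives, between 0.15 and 0.64. The related families of miR-99, miR-100, miR-125 and miR-10 split. miR-99a-5p was higher, miR-125b-5p was 1.96-fold higher (0.97 ± 0.097), and miR-100-5p was detected in shGATA3 only. In contrast, miR-99b-5p was 1.70-fold lower (-0.77 ± 0.14) and miR-125a-5p had a difference of -0.36 ± 0.11. The median of the 4 shared members was 0.31, at percentile 85.1, and turned to -0.36 when only bright miRNAs were kept, a setting that left out miR-99a-5p.

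Of the miRNAs linked to oestrogen-receptor-positive or luminal tumours, 4 of 7 were detected on both arrays, with a median of -0.45 at percentile 9.23. miR-342-3p and miR-375 (1.90-fold lower, -0.93 ± 0.14) were lower, while miR-26a-5p (0.032 ± 0.085) and miR-26b-5p (0.17 ± 0.097) were not. The median was 0.032 when only bright miRNAs were kept, a setting that left out 1 of the 4. Among miRNAs reported to target ESR1, the oestrogen receptor gene, 2 of 5 were higher, led by miR-22-3p (0.58 ± 0.12), and 3 were lower, led by miR-18a-5p (-0.53 ± 0.22). Their median of -0.29 lay at percentile 18.0 and was 0.023 with the hybridisation spike-ins.

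The tumour-suppressive let-7 family was lower in 8 of 9 members, from miR-98-5p at -0.093 to let-7e-5p at -0.51, with let-7c at 0.12, but in only 2 of 9 without scaling or with the hybridisation spike-ins. Its median of -0.20 lay at percentile 42.55 and was only -0.088 relative to the median of all miRNAs. The median itself turned to 0.077 without scaling and to 0.11 with the hybridisation spike-ins. The miR-200 family, which maintains the epithelial state, had members on both sides, from miR-200c-3p at -0.39 ± 0.12 to miR-141-3p at 0.35 ± 0.13. Its median of 0.056 lay at percentile 73.91 and lay below 0 in 4 of the 14 alternatives. All 3 members of the miR-29 family were higher (2 of 3 with quantile normalization, the total signal, the deposited table or all spots above background), with a median of 0.26 at percentile 81.43. The medians of the miR-30 family (0.061, percentile 70.08), miR-15/16 family (-0.0038, percentile 67.87), miR-183 to miR-182 cluster (0.21, percentile 82.55) and miR-181 family (-0.0021, percentile 57.52) lay inside the range of random lists. Relative to the median of all miRNAs, miR-15/16 and miR-181 were each at 0.11. The sign of the median turned in 4 of 14 alternatives for the miR-30 family, in 7 of 14 for miR-15/16, in 6 of 12 for miR-181 and in 0 of 13 for the miR-183 to miR-182 cluster.

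**Figure D3:**
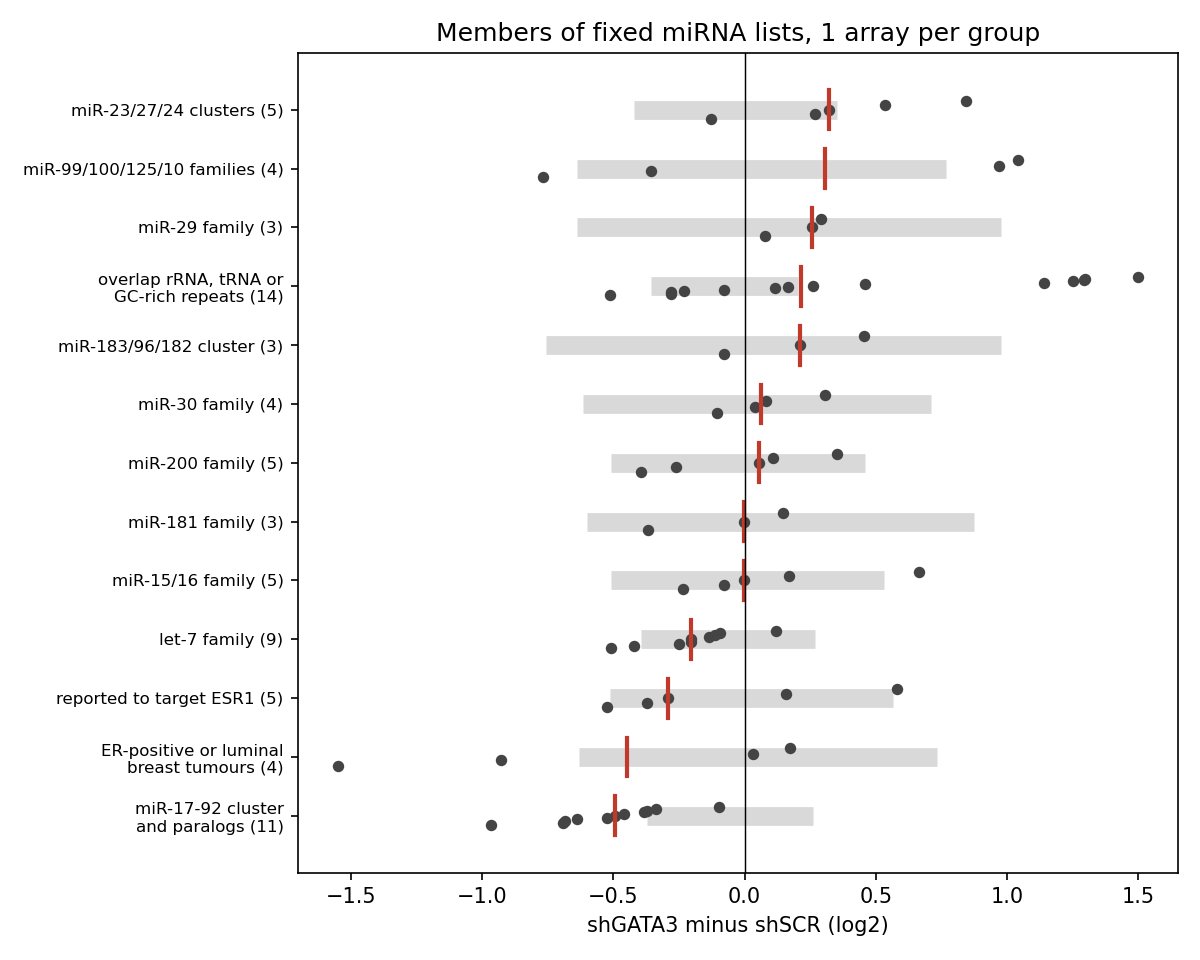
Differences between shGATA3 and shSCR (log2, horizontal axis) of the detected members (points) of 13 fixed lists, with the list median in red and the central 95% of medians of random level-matched lists in grey. In the main setting shown, all 11 points of the miR-17-92 group lie below 0 (10 without scaling or with hybridisation spike-ins), and its median of -0.49 lies below the grey range.

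The last list was fixed as 14 annotated miRNAs that overlap rRNA, tRNA or GC-rich repeats, and all 14 were detected on both arrays. The overlaps were not checked here against sequences. In shGATA3, 9 were higher and 5 lower, against 13 and 1 with the hybridisation spike-ins and 7 and 7 with normexp. The 5 that were at least 2-fold higher were miR-3960, miR-762, miR-3665, miR-1915-3p and miR-4466, of which miR-4466 (1.14) lay within 2-fold with normexp (0.39), the total signal (0.98), the deposited table (0.97), its brightest probe (0.96) and all spots above background (0.97). Those that were lower included miR-1260a (-0.51 ± 0.16) and miR-4454 (-0.28 ± 0.071). The list median of 0.21 lay at percentile 97.78, just above the upper limit of 0.205 of the central 95% of random lists. It lay between 0.046 and 0.53 over the 14 alternative settings. Of the smaller lists, miR-222-3p and miR-455-5p were not well above background on either array, miR-221-3p had a difference of 0.16 ± 0.35 and the p53-responsive miR-34a-5p one of -0.25 ± 0.16. Among miRNAs of liver, muscle, heart or brain, miR-219-5p alone was detected on both arrays (-0.19 ± 0.33). None of the 7 stromal miRNAs, none of the 6 blood-cell miRNAs other than miR-486-5p and none of the 13 measured miRNAs of the chromosome 19 primate cluster was detected, and of the chromosome 14 imprinted cluster miR-134 alone was, in shGATA3 only.

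For miRNAs detected on 1 array only, a bound was set by the lowest detected signal of the other array or the probe's own, whichever was higher. miR-3944-5p was at least 8.02-fold higher in shGATA3, miR-9-3p at least 3.78-fold, miR-3940-5p at least 2.20-fold by 1 of its 2 probes, miR-4763-3p at least 2.12-fold and miR-134 at least 1.92-fold. The 5 largest bounds of miRNAs detected in shSCR only were smaller than these 5, and some others, such as miR-339-5p, had no bound in the main setting. Other miRNAs detected in shGATA3 only also had small bounds, such as miR-3652 at 1.23-fold. Unlike miR-9-3p, miR-9-5p was not well above background on either array. miR-93-3p was at least 1.70-fold higher in shSCR by 1 of its 4 probes, miR-455-3p at least 1.49-fold by 1 of its 2 probes, miR-4701-3p at least 1.33-fold, miR-17-3p at least 1.20-fold by 1 of its 2 probes and miR-4442 at least 1.15-fold. No bound was left for miR-17-3p and miR-4442 without scaling or with hybridisation spike-ins, where the log2 bounds of miR-93-3p were 0.48 and 0.45, of miR-455-3p 0.30 and 0.26 and of miR-4701-3p 0.13 and 0.093, against 0.76, 0.58 and 0.41 in the main setting. The counts of 19 and 14 depended on the detection rule, and were 72 and 28 where any single spot above background sufficed.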

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

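All tests of the higher miRNAs in this part were chosen after the result was seen, apart from that on tRNA and rRNA fragments. The control features were not part of the comparison, and 3 of them were brighter in shGATA3 than in shSCR by more than their spot SD before scaling. These were the labelling spike-ins dmr_285 (0.25) and dmr_31a (0.12) and the corner feature miRNABrightCorner30 (0.52, spot SD 0.29), all as log2 differences. The hybridisation spike-ins dmr_3 (-0.083) and dmr_6 (0.013) were within their spot SD, while the controls hur_6 (-0.27, spot SD 0.059) and hur_4 (-0.17, spot SD 0.039) were lower in shGATA3 by more than theirs.

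The miRNAs at least 2-fold higher in shGATA3 were the pattern weighed first. The spike-ins could not test a single brightness factor between the arrays, since the scaling had already removed any such factor from the counted differences. Before scaling, their mean offset per pair was at most 0.1873 on the log2 scale, with dmr_285 alone at 0.25 and the corner feature at 0.52. A uniformly higher background left in the processed signals of the shGATA3 array is argued against by the negative-control spots. Their median was lower there (difference -2.852 intensity units, interquartile ranges 5.22 and 4.09), whereas the probes of the higher miRNAs were brighter by at least 22.6 units after scaling. The size of that excess follows in part from the 2-fold limit and the detection rule that chose these miRNAs. The control spots were read after background subtraction, so the background before it was not compared. Over all 1000 negative-control spots, outlier-flagged ones included, 1.5% were well above background in shGATA3 and 0.4% in shSCR. Spots flagged for a non-uniform background numbered 94 in shGATA3 and 0 in shSCR, so the medians do not exclude a patchy background. The tests on spike-ins and negative controls replaced earlier ones on the list of miRNAs that overlap rRNA, tRNA or GC-rich repeats. Their limits were set with the control values in view. What stays open is RNA quality, labelling that differs between sequences, and the hairpin itself, since there was 1 array per group.

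For that list, the earlier test of a brightness factor did not decide, because its percentile of 97.78 lay within a spot SD of the limit of random lists. The earlier test of background used the 8 members brighter than the median miRNA, and their median of 0.3604 met the limit of under 0.5 that had been set for a background. That limit had also required the rise to lie in the dim members, whose median was 0.14, and members of both sets went both ways. The verdict against a uniform background left after subtraction therefore rests on the medians of the negative controls alone. More tRNA and rRNA fragments in general were tested only on the 5 members not chosen for GC-rich sequence, whose origin from tRNA or rRNA was not checked here. Their median was -0.2294 (4 of 5 lower, with miR-1246 higher at 0.26). In the main setting this argues against a rise of these 5 members, and other fragments were not tested. That median was at most 0.087 over all settings. It was above 0 in 2 of them, without scaling and with the hybridisation spike-ins, where it lay between the limits set beforehand and did not decide.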

How the results depend on the processing

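The scalings on labelling spike-ins, on hybridisation spike-ins and on miRNAs numbered under 1000 were chosen after the data were seen, as were those of the bounds. The count of higher miRNAs was within 1.5 times 17 in 10 of 14 processing settings, and was 27 without scaling and with hybridisation spike-ins, 5 with normexp and 9 when only bright miRNAs were kept. The count of lower miRNAs (5) was 2 without scaling, with hybridisation spike-ins and with only bright miRNAs, 1 with normexp, 18 with the software's total signal, 20 in the deposited table and 9 where all spots had to be above background. At 1.5-fold, 32 were higher and 23 lower, and at 3-fold 2 and 0. miRNAs detected in shGATA3 only (19) were 72, and those in shSCR only (14) were 28, where any spot sufficed, and by the software's own call 26 were detected in shGATA3 only, of which 11 were shared, and 28 in shSCR only, of which 3 were shared. The bright filter tests fewer miRNAs (118), and the cause was not tested for the others. All 17 named miRNAs past 2-fold on both arrays kept their sign in every setting that measured them, but 3 of the 5 lower ones lay within 2-fold without scaling and with hybridisation spike-ins, and 4 lower and 7 of the 12 higher ones with normexp. The bounds of miR-17-3p and miR-4442 were lost without scaling and with hybridisation spike-ins.

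The scalings moved the median of all miRNAs by up to 0.32 on the log2 scale (hybridisation spike-ins; 0.28 without scaling), so list medians were compared relative to the median of all miRNAs. This was decided after the medians as planned, without that reference, had been seen. As planned, 113 of 178 list values stayed within the spot SD, 60 moved further and 5 larger than it changed sign (26 changed sign at any size): let-7 without scaling (0.077) and with hybridisation spike-ins (0.11), ESR1-targeting with hybridisation spike-ins (0.023), and luminal (0.032) and the miR-99 to miR-10 families (-0.36) with only bright miRNAs. Relative to all miRNAs, 78 values could not move, because 6 settings shift every miRNA alike, and 90 of the other 100 stayed within it. With normexp, miR-17-92 was at -0.26, miR-29 at 0.22, luminal at -0.13 and the miR-99 to miR-10 families at 0.26. Without a dim filter, luminal was at -0.12 and the miR-99 to miR-10 families at 0.16. The miR-99 to miR-10 families were at 1.09 with the total signal and in the deposited table, where they had 5 members in place of 4. With only bright miRNAs, which left 3 members in each, luminal reversed to 0.16 and the miR-99 to miR-10 families to -0.23. No paired analysis was possible because each group had 1 array. About 11% of spots were well above background, so differences near the floor were measured least well.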

Other observations

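Of the tests in this part, those on scaling and on single probes were chosen after the result was seen. Several miRNAs outside the fixed lists, picked here after their values were seen, lay close to 2-fold. miR-7-5p, an abundant miRNA of neuroendocrine cells, was 1.89-fold lower in shGATA3 (-0.92 ± 0.15) and miR-3934-5p 1.82-fold lower (-0.86 ± 0.23). miR-642a-3p was 1.97-fold higher (0.98 ± 0.093). The growth-associated miR-21-5p, among the brightest miRNAs on both arrays, had a difference of 0.23 ± 0.13. Within the listed miR-15/16 family, miR-424-5p was 1.59-fold higher (0.66 ± 0.17).

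The lower levels of miR-342-3p, miR-205-5p and miR-210 are the second pattern weighed. The test of scaling could hardly have failed, because the scalings moved the median of all miRNAs by at most 0.32 and its limits followed the values. It shows only how far the differences moved. The difference closest to 0 was -0.9241, that of miR-210 with hybridisation spike-ins, which is within 2-fold. miR-342-3p (-1.23) and miR-205-5p (-1.22) were still past 2-fold there. For these 3 miRNAs the differences did not come from 1 deviating probe, since the probe difference closest to 0 was -1.224. The naming rule had already required shared probes to go the same way, so the test could fail only by size. It did not cover the other lower miRNAs, miR-1275, with probes at -1.37 and -0.95, and miR-652-3p, with 1 shared probe. Variation between cultures or array positions cannot be told apart from an effect of the hairpin with 1 array per group. Testing an effect of the hairpin would need further replicates. GATA3 was not measured here, so an effect of GATA3 loss cannot be told apart from other effects of the hairpin.

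A hypothesis was that miRNAs from neighbouring genes differ together. For miR-99a-5p and miR-125b-5p it was tested on let-7c, whose gene neighbours that of miR-99a and, further off, a gene of miR-125b. Its difference of 0.118 in the main setting did not decide between the limits set beforehand (0 and 0.5), and its 2 probes had opposite signs (-0.062 and 0.30). With the brightest probe, the total signal, the deposited table or all spots above background, all 9 let-7 members lay below 0. let-7c thus met the limit against the hypothesis there, so the outcome depended on the setting. In the main setting let-7c lay 0.92 from miR-99a-5p. let-7a-5p, of which 1 gene neighbours another gene of miR-125b, had a difference of -0.25, a gap of 1.22 from miR-125b-5p, but it is also made from other genes, so that pair does not decide either. Across 49 pairs of miRNAs of different families within 50 kb, the median gap of 0.31 lay at percentile 1 of random pairs, and at 6.70 against miRNAs numbered under 1000. Without pairs inside the miR-17-92 group, the percentiles were 5.84 and 17.2, so the hypothesis stays open, also because pairs share miRNAs. The matching of names to genes and of families was corrected more than once after results had been seen, with percentiles first above and then below the present ones.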
